A study of Mus musculus with 15 samples.

How the data were processed

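The series holds 15 mouse single-cell RNA-seq libraries from hearts at embryonic days 7.75, 8.25, 8.75 and 9.25. Per the labels, cells came from mice carrying Nkx2-5Cre or Isl1Cre together with the Rosa26tdTomato reporter, which stays on in a cell and its descendants once Cre has acted. The lineage and the stage of each library were read from its title and its stage label, which gave 8 groups. Each group has 2 libraries, except Isl1Cre at E9.25, which has 1. In 7 of the 8 groups both titles carry the same embryo number, so the libraries of a group probably came from 1 embryo. The p-values therefore measure only the spread between libraries, which may be technical, and a difference between lineages or stages cannot be separated from a difference between single embryos.

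Per the labels' protocols, cells were sorted by FACS or only dissociated with trypsin, and were then picked by mouth pipette; which of these was used for which library is not given in the sources used here. Reverse transcription used an oligo(dT) primer with an 8-nt cell barcode and an 8-nt unique molecular identifier in a modified Smart-seq2 protocol, the 3' ends of the cDNA were captured, and libraries were sequenced as 150-bp paired ends on a HiSeq X. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12, HTSeq and the mm10 genome, with no parameters. The deposited values are CPM (each count scaled by the total of its cell) per gene and cell, computed by the authors, for 23154 genes in every file; no mitochondrially encoded gene is among them.

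CPM is not a count, so the values were first examined for the step that 1 count is worth in each cell. In every library 100% of the low values (up to 20 steps) were whole multiples of that step within a tolerance of 0.1 of a step, so whole counts were recovered for every cell. Whether they are reads or molecular identifiers is not stated; intervals and floors cover counting error only. The count tests planned before the data were examined assumed deposited counts. Because the deposited unit is CPM, the main tests were run on CPM and the count tests became alternatives: edgeR was added after the unit was known, and DESeq2 had been planned.

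Of 1400 cells, 1332 had at least 2000 counts and at least 1000 detected genes and were kept, 738 of Nkx2-5Cre and 594 of Isl1Cre. No doublet caller was run, since cells were picked singly; doublets were not otherwise removed. Library totals over kept cells ranged from 8165519 counts (Isl1Cre E8.75 replicate 1, which kept 61 of 80 cells) to 38321215 (Nkx2-5Cre E7.75 replicate 1). The median kept cell had 121298 counts and 5873 genes, and the 10 deepest cells held 27.9% to 47.4% of a library's counts. Each library was therefore summarised as the mean CPM over its kept cells, which weights cells equally. No 2 libraries of a group agreed within counting noise: the chi-square divided by its degrees of freedom was 17.8 to 63.5, and r across genes of the log2 values was 0.954 to 0.973. The chi-square leaves out the drawing of different cells, which alone can raise it, so it cannot show disagreement beyond that.

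Kept cells were scaled to 10000 counts, log-transformed and clustered (2000 variable genes, 30 principal components, 15 nearest neighbours, Leiden resolution 1.0; leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 in Python 3.11.15). No cell annotation was used. Clusters were named from marker lists fixed before the data were examined. The naming rule was chosen after seeing the data: the class with the most markers (at least 1) among a cluster's 10 leading genes gave the name, provided that at least 3 of its markers, and a share of at least 0.5 of them, were at least 2-fold above the median of the other clusters (mean CPM + 10) and seen in at least 25% of the cluster's cells. No cluster reached the planned progenitor class, so the planned tests within it were not run. Shares of classes were compared by exact two-sided permutation tests, permuting lineage within stages or stages within a lineage, with Benjamini-Hochberg adjustment over classes or over classes and lineages.

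Genes were tested with limma 3.58.1 (trended empirical Bayes, R 4.3.3) on log2(mean CPM + 1) after TMM scaling (factors 0.955 to 1.042), for the 10665 genes with a mean of at least 5 CPM in at least 2 libraries. The model had 1 mean per group and 7 residual degrees of freedom over the 15 libraries, so the single Isl1Cre E9.25 library was assumed to vary like the others. Contrasts were Isl1Cre minus Nkx2-5Cre averaged over the 4 stages, the same difference at each stage, the linear change per day in each lineage, and the difference between these slopes. Within cardiomyocyte-like cells, 11 libraries with at least 10 such cells (6 Nkx2-5Cre, 5 Isl1Cre) and 10223 genes were tested with stage or lineage as an additive term. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All gene p-values below are these adjusted limma values unless a sentence names another test. Changes are on the log2(CPM + 1) scale, which understates changes of low genes, and are given with standard errors.

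Named genes followed a rule fixed before the data were examined: for each test the 6 largest positive and 6 largest negative called changes with an average log2 level of at least 5, leaving out predicted-gene, Riken and pseudogene symbols (for the lineage contrast only genes whose group means differ the same way in at least 3 of 4 stages); a panel of 24 genes; and up to 4 members of each described list with the smallest adjusted p. Results of a few genes that this rule names are not reported here. Of 37 gene lists fixed in advance, 34 had at least 5 tested members, a minimum chosen after seeing the data; nascent mesoderm, mitochondrially encoded and neural crest lists were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast. Alternatives were camera with an estimated correlation, fry, a replicate block, and groups pooled to 1 unit. Camera compares a list with all other genes; fry tests whether its genes move, on balance, in 1 direction. List members were also counted after adjustment over the list alone.

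Alternatives for the gene tests were RLE scaling, no scaling beyond CPM, pseudocounts of 0.1 and 10, no filter on low values, cells with at least 3000 genes, libraries or cells thinned to a common depth (5000 counts per cell), a replicate block, groups pooled to 1 unit, each library left out, edgeR 4.0.16 and DESeq2 1.42.0 on summed recovered counts, and other clusterings. The pseudocounts, the unscaled values, leaving out E7.75, E8.25 or cluster 4, and pooling in the list tests were chosen after seeing the data. So was the use of edgeR, the planned main test, as an alternative. Gene positions came from GENCODE vM21 (GRCm38, the mm10 build), in which 22113 of the 23154 symbols matched 1 location. The strand setting of the counting is not stated, so overlapping and antisense genes (such as Atcayos) may share counts. So may genes of similar sequence (globins of 1 family, actins, the myosin heavy chains Myh6 and Myh7).

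The tests were tested on simulated counts with 200 changed genes drawn from these libraries' means. For the lineage contrast (10211 genes run) 67% of 2-fold and 94% of 4-fold changes were recovered, and 5.3% of calls were false. For single stages, recovery of 2-fold changes was 29% at E7.75 (10223 genes run), 31% at E8.25 (10244), 30% at E8.75 (10223) and 13% at E9.25 (10239); of 4-fold changes it was 76%, 72%, 79% and 48%. For slopes the changes were 2-fold and 4-fold per day. Their recovery was 65% and 88% for the Nkx2-5Cre slope (10212 genes run) and 44% and 80% for the Isl1Cre slope (10242). It was 36% and 68% for the difference of slopes (10261) and 37% and 84% for stage in cardiomyocyte-like cells (9882). For lineage in those cells 53% of 2-fold and 88% of 4-fold changes were recovered (9887). False calls made up 2.8% to 7.6% of calls over all 10 contrasts. The simulation drew 1 total per gene and library with the spread between these libraries. It therefore covers neither the averaging over cells nor differences between embryos. A simulated changed list of 30 genes was called, and 0 of 20 unchanged lists were.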

Results

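RNA was measured in single heart cells of mouse embryos at embryonic days E7.75, E8.25, E8.75 and E9.25. In these embryos Cre recombinase, named for the heart transcription factor gene Nkx2-5 or for Isl1, switches on a red fluorescent reporter that the cells' descendants keep. The series asks how lineages of the second heart field are ordered and how they communicate while its cells join the heart; the comparisons below are between the Cre lineages at matched stages and between stages within a lineage. Each of the 8 groups held 2 libraries, except Isl1Cre at E9.25 with 1 library. Of 1400 cells in the 15 libraries, 1332 were kept, and the total recovered count per library was between 8165519 and 38321215. Levels are mean CPM over the kept cells of a library, given as mean ± SD over the libraries of a group (n = 2; no SD for Isl1Cre E9.25). Changes are log2 changes ± SE with limma adjusted p-values.

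The kept cells formed 11 clusters, and 8 of them could be named from markers. Clusters 1, 2, 4, 6 and 7 were cardiomyocyte-like. Cluster 1 (267 cells) was led by the natriuretic peptide genes Nppa and Nppb, cluster 2 (192 cells) by Myh7, Tdgf1 and Pyy, cluster 4 (140 cells) by Trdn, Mest and Etv2, cluster 6 (133 cells) by Gal and Tnni3, and cluster 7 (95 cells) by Cck, Nppa and Myl2. Etv2 in cluster 4 is an endothelial marker. The cells of cluster 4 had a median count 0.63 times that of their libraries. Of its 140 cells, 39 formed a cluster of their own at resolution 1.5, with a median of 2917 counts (2058 to 13983). They were 5 of the 103 cells of cluster 4 in Isl1Cre E8.25 and 6 of the 9 in Nkx2-5Cre E8.25, and all those of the other 6 groups. Clusters 8 (81 cells; Gngt2, Ets1, Plvap) and 11 (34 cells; Etv2, Ets1, Flt4) were endothelial-like, and cluster 9 (40 cells; Spink1, Ttr, Apela) was endoderm-like. The other 350 cells stayed unnamed. Of these, cluster 3 (175 cells; Apoa1, Sfrp5, Ifitm1, Fgf8) took 163 cells from Nkx2-5Cre E7.75, and cluster 5 (138 cells; Sfrp5, Ifitm1, Ntng1, Pdgfra) took 135 from Isl1Cre E7.75. Both also held contractile RNA, with Tnnt2 at 1948.7 and 1379.3 CPM and Myl7 at 4700.5 and 3143.0 CPM, so the absence of a name is no absence of these genes. Cluster 10 (37 cells, led by Hoxaas3, Pitx1, Etv2 and Hoxb6) took 35 from Isl1Cre E8.25. The named classes were the same at Leiden resolutions 0.6 and 1.5.

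Cells named cardiomyocyte-like were few at E7.75 and made up most cells from E8.25 on. In Nkx2-5Cre their share was 1.1% ± 1.5 at E7.75, 85.0% ± 3.1 at E8.25, 93.5% ± 2.8 at E8.75 and 82.6% ± 2.8 at E9.25 (SD, n = 2). In Isl1Cre it was 1.7% ± 0.7, 67.7% ± 0.0 and 88.7% ± 0.3 at the first 3 stages, and 97.8% (exact 95% binomial interval 92.29% to 99.73%) in the single E9.25 library. The 2 and 3 cells of this class at E7.75 were all among the shallow cells of cluster 4. Unnamed cells made up 88.1% ± 1.3 of Nkx2-5Cre and 77.9% ± 8.0 of Isl1Cre cells at E7.75, and 5.3% against 20.4% at E8.25. Endoderm-like cells were 6.5% ± 3.2 of Nkx2-5Cre and 8.0% ± 1.3 of Isl1Cre cells at E7.75, and 7.5% ± 3.0 of Isl1Cre cells at E8.25. None was seen in the other 9 libraries, which allows a share of up to 3.85% to 5.87% in each (upper end of the exact 95% binomial interval). Endothelial-like cells were 17.4% ± 2.8 of Nkx2-5Cre cells at E9.25 and 2.2% of the Isl1Cre library (interval 0.27% to 7.71%). How cells were sorted and picked can set such shares.

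**Figure D1:**
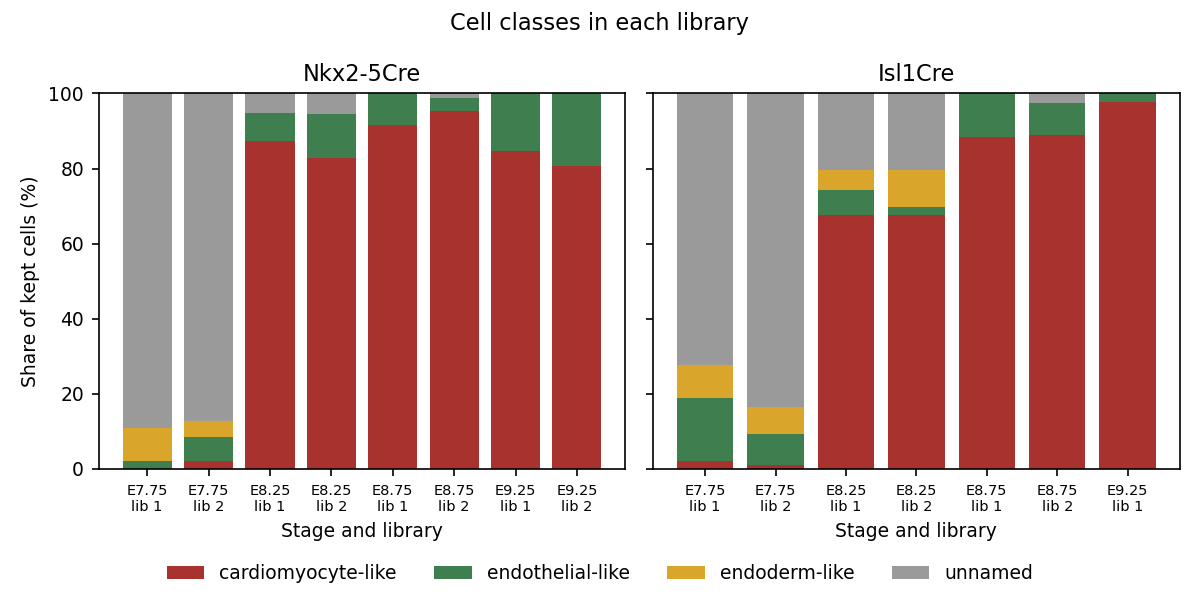
Share of kept cells (%, vertical axis) in each cell class by lineage, embryonic day and library (horizontal axis); each bar is 1 library, with the classes stacked in colours. The mean share of cardiomyocyte-like cells goes from 1.1% (Nkx2-5Cre) and 1.7% (Isl1Cre) at E7.75 to 82.6% and 97.8% at E9.25.

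The shares did not separate the lineages when averaged over stages. Cardiomyocyte-like cells averaged 64.0% in Isl1Cre and 65.5% in Nkx2-5Cre (exact permutation p = 0.744, two-sided, 648 arrangements). Endothelial-like cells averaged 7.3% and 9.3% (exact p = 0.593, adjusted 0.744), and endoderm-like cells 3.9% and 1.6% (exact p = 0.111, adjusted 0.333). With stage, the cardiomyocyte-like share rose by 67.66 points per day in Isl1Cre (exact p = 0.00159, adjusted 0.00952, 630 arrangements). The slope in Nkx2-5Cre was 50.63 points per day (exact p = 0.046, adjusted 0.069, 2520 arrangements), and did not pass. Both slopes depend on the naming rule, which was chosen after seeing the data and compares a cluster with the median of the others. It left clusters 3 and 5, mostly cells of E7.75, unnamed although they held Tnnt2 at 1948.7 and 1379.3 CPM. All these share tests permuted single libraries, and those of a group probably came from 1 embryo. Parting such libraries favours the real order in advance, so the exact p-values cannot show a trend beyond differences between embryos. Endothelial-like slopes were 7.11 points per day in Nkx2-5Cre (exact p = 0.0437, adjusted 0.069) and -4.4 in Isl1Cre (exact p = 0.284). Endoderm-like slopes were -3.91 (exact p = 0.0714, adjusted 0.0857) and -6.68 (exact p = 0.0238, adjusted 0.069). The Isl1Cre cardiomyocyte-like slope no longer passed without replicate 1 or 2 at E7.75 (60.33 and 59.76 points), replicate 1 or 2 at E8.75 (66.39 and 66.3) or the E9.25 library (87.01). The Nkx2-5Cre slope passed at 61.19 without E9.25 replicate 2. The Nkx2-5Cre endothelial-like slope passed at 8.02 without its E8.75 replicate 2, and the Isl1Cre endoderm-like slope, through the adjustment, at -6.68 without either of these 2 libraries.

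Averaged over the 4 stages, 24 of 30 sarcomere genes were lower in Isl1Cre than in Nkx2-5Cre cells. That list was 1 of 16 called, none of which passed with an estimated correlation (adjusted p = 0.0567 for sarcomere genes), and its median was 0.39 at E9.25. Of 10665 genes, 784 differed, 392 higher and 392 lower in Isl1Cre. Isl1 itself (chromosome 13, 116298281 to 116309689, mm10), a transcription factor gene of second heart field progenitors, was lower in Isl1Cre (-1.0 ± 0.21, adjusted p = 0.00755). Its group means were lower at each stage: 52.8 ± 2.6, 17.1 ± 10.5, 11.7 ± 5.3 and 28.1 ± 0.3 CPM in Nkx2-5Cre against 34.7 ± 9.3, 11.5 ± 1.9, 6.2 ± 1.6 and 5.0 CPM. By single stage it did not pass at E7.75, E8.25 or E8.75 (limma adjusted p = 0.462, 0.635 and 0.443). At E8.25 1 Nkx2-5Cre library (9.7 CPM) lay below both Isl1Cre libraries (10.2 and 12.9 CPM). The difference was largest at E9.25 (-2.21), with 1 Isl1Cre library. Nkx2-5 (chromosome 17, 26838664 to 26845009) was higher (0.28 ± 0.09, adjusted p = 0.0492), at 3 of 4 stages. Among called genes with an average log2 level of at least 5 and 1 direction at 3 or more stages, the largest positive changes were in Mpv17l (1.39 ± 0.13), the let-7 regulator gene Lin28a (1.16 ± 0.13), the kinase gene Wnk1 (1.08 ± 0.12), BC024978 (1.07 ± 0.26), the zinc finger gene Sall4 (1.04 ± 0.11) and the ubiquitin ligase gene March5 (1.02 ± 0.09), with adjusted p from 5.1e-06 (March5) to 0.0163 (BC024978). Lin28a was at 216.9 ± 16.7 CPM in Nkx2-5Cre and 410.1 ± 7.5 in Isl1Cre at E7.75. In the same set the largest negative changes were in the integrin gene Itga6 (-1.01 ± 0.17), Casq1 (-0.91 ± 0.18), Pbxip1 (-0.90 ± 0.14), the sarcomere gene Actn2 (-0.90 ± 0.11), Dpysl3 (-0.89 ± 0.12) and Tnni3 (-0.85 ± 0.09), with adjusted p from 1.78e-05 (Tnni3) to 0.00398 (Casq1). Of 23 tested panel genes 9 passed, and 14 adjusted over the list alone. They included Tnnt2 (-0.25 ± 0.06), Myl7 (-0.28 ± 0.05), Myl2 (-0.53 ± 0.10), Myh6 (-0.49 ± 0.09), Myh7 (-0.47 ± 0.09) and Nppa (-0.90 ± 0.16), and the chemokine receptor gene Cxcr2 (0.90 ± 0.12, adjusted p = 0.00025). Mif, which encodes a cytokine that can bind Cxcr2, was at 0.02 ± 0.05 (adjusted p = 0.847). The 6 lower panel genes were not lower at all stages. At E9.25 Tnnt2 was at 0.40, Myl7 at 0.25, Myl2 at 0.67, Myh6 at 0.31, Myh7 at 0.73 and Nppa at 0.17 (adjusted p = 0.11 to 0.908), and at E8.75 Myl2 was at 0, Myh7 at 0.25 and Nppa at 0.09. Myh7 was at 0.07 (adjusted p = 0.784) with the E7.75 libraries left out.

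By list, 24 of 30 sarcomere genes were lower in Isl1Cre and none higher (25 adjusted over the list alone; median -0.44, camera adjusted p = 9.49e-25, adjusted p = 0.0567 with an estimated correlation), among them Myl3 (-0.75 ± 0.06) and the smooth muscle actin gene Acta2 (-0.50 ± 0.06). Of 17 ventricular genes 8 were lower (9 adjusted over the list alone; median -0.50, adjusted p = 3.13e-09, adjusted p = 0.0567 with an estimated correlation), including Cck (-0.84 ± 0.10) and Lbh (-0.84 ± 0.12). Of 77 nuclear-encoded oxidative phosphorylation genes 17 were lower and 3 higher (28 and 3 adjusted over the list alone; median -0.13, adjusted p = 2.27e-09, adjusted p = 0.228 with an estimated correlation); Sdhc (0.64 ± 0.11) was among those higher. Of 10 epiblast genes 5 were higher (5 adjusted over the list alone, median 0.54, camera adjusted p = 0.000254, adjusted p = 0.0567 with an estimated correlation), Nanog (0.83 ± 0.20) and Trim71 (0.54 ± 0.15) among them. The list name does not mean epiblast cells. Pou5f1 and Sox2 were at most 4.6 and 5.0 CPM in any cluster, and Nanog lay at 15.8 to 68.8 CPM across all clusters. Of 42 G2 and M phase genes 6 were higher (6 adjusted over the list alone; median 0.19, adjusted p = 1.94e-06, adjusted p = 0.193 with an estimated correlation). Of 15 endoderm genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone; median 0.58, adjusted p = 0.000285, adjusted p = 0.193 with an estimated correlation), beside a higher level of the epithelial cadherin gene Cdh1 (1.15 ± 0.32). Of 16 outflow tract genes 4 were lower (5 lower and 1 higher adjusted over the list alone; median -0.38, adjusted p = 0.000459, adjusted p = 0.0567 with an estimated correlation), led by Tgfb2 (-0.84 ± 0.12).

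The other lists called in the lineage contrast were lower for glycolysis and hypoxia (5 of 25; median -0.21, adjusted p = 4.34e-05), extracellular matrix (6 of 32; median -0.32, adjusted p = 0.000188; Fbn1 at -1.21 ± 0.20), blood (2 of 8; median -0.51, adjusted p = 0.00514), calcium handling (3 of 19, with 1 higher; median -0.27, adjusted p = 0.00864) and BMP and TGF-beta (4 of 18; median -0.12, adjusted p = 0.025; Msx2 among them). They were higher for epithelial junctions (5 of 18; median 0.34, adjusted p = 0.000197), Hox genes (2 of 14; median 0.67, adjusted p = 0.00159), surface ectoderm (3 of 6, with 1 lower; median 0.69, adjusted p = 0.00159) and the posterior second heart field (2 of 18; median 0.33, adjusted p = 0.00509; Osr1 and Hotairm1). Adjusted over the list alone, the same lists held, in this order, 14 lower and 1 higher, 10 and 1, 2 and 0, 5 and 1, 4 and 0, then 6 higher and 0 lower, 2 and 0, 5 and 1, and 7 and 1. With an estimated correlation none of these 9 lists passed, with an adjusted p of 0.0567 to 0.193. Not called were S phase (adjusted p = 0.0696), dissociation stress (0.0727), ribosomal proteins (0.075), endothelial (0.121), cranial and pharyngeal mesoderm (0.121), atrial and inflow (0.174), first heart field (0.231), anterior second heart field, FGF, migration and proepicardial (each 0.293), mesenchymal and cushion (0.313), hedgehog (0.343), chemokine and MIF (0.865), retinoic acid (0.889), Wnt and neural (each 0.94) and Notch (0.992). For the retinoic acid list the median (-0.05) and the mean (0.05) differ in sign, as they do for Wnt. Taken stage by stage, the endoderm, epithelial junction, Hox and surface ectoderm lists passed at E8.25 and not at the other stages, which is no test of a difference between stages. Of these, the epithelial junction list did not pass at E8.25 with an estimated correlation. The endoderm, epithelial junction and surface ectoderm lists share Epcam, Cdh1, Krt8 and Krt18, so their results are not independent. The sarcomere median was -1.32, -0.78, -0.10 and 0.39 at the 4 stages. The chemokine and MIF list was drawn up partly from the subject of the study, so it is not independent evidence; 1 of its 7 tested genes, Cxcr2, was higher.

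These counts rest on the spread between libraries of probably 1 embryo per group. With the libraries of a group pooled to 1 unit, limma called 0 genes for the lineage contrast (874 at an unadjusted p under 0.05; with all 15 libraries edgeR called 740 and DESeq2 1057), against 784. With the E7.75 libraries left out it called 260, with those of E8.25 left out 458, and with cells thinned to 5000 counts 216.

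**Figure D2:**
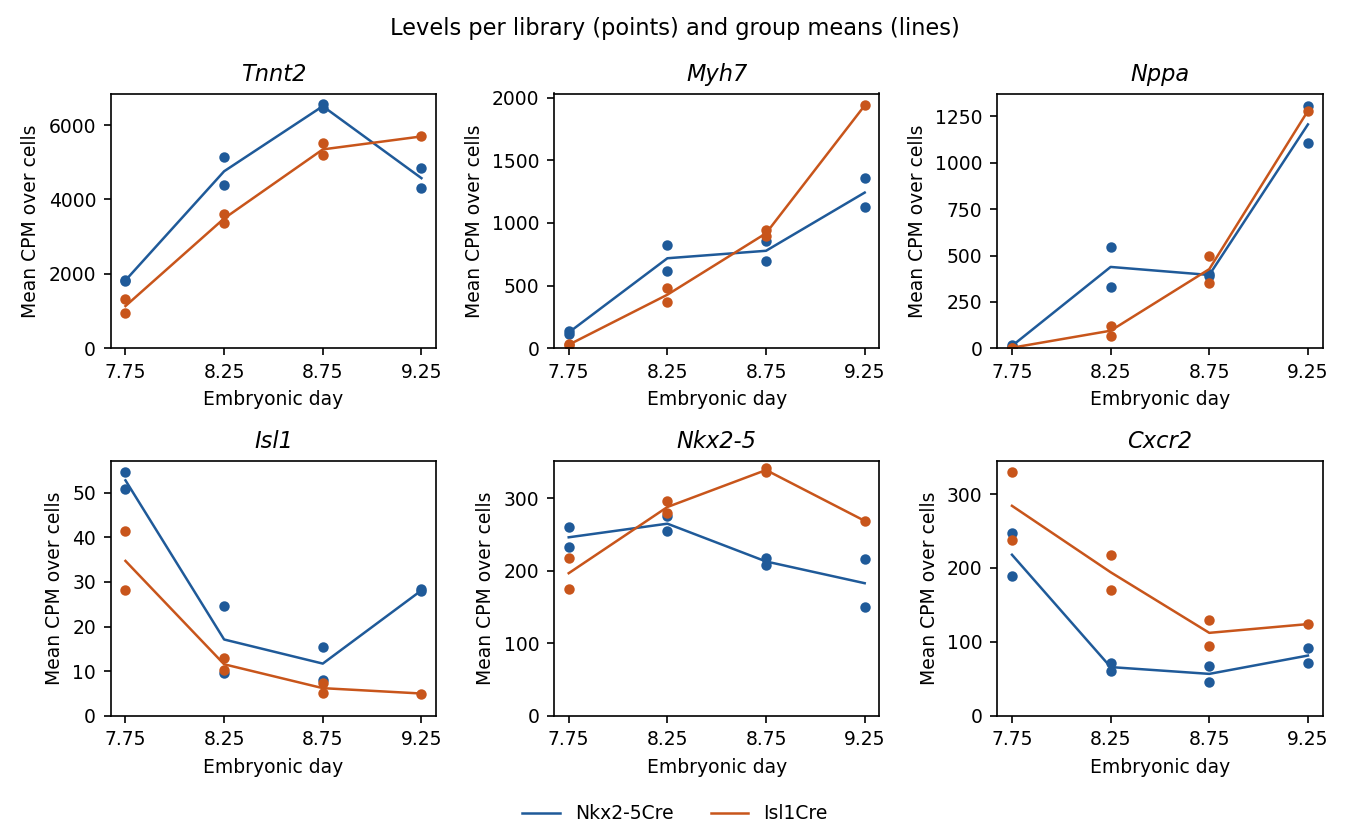
Mean CPM per library (vertical axes, CPM) of Tnnt2, Myh7, Nppa, Isl1, Nkx2-5 and Cxcr2 against embryonic day, for Nkx2-5Cre and Isl1Cre; each point is 1 library and lines join group means. Myh7 lies at 126.3 CPM in Nkx2-5Cre and 28.6 in Isl1Cre at E7.75, and at 1242.3 and 1936.8 at E9.25.

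At E7.75 the RNA of most sarcomere genes was lower in Isl1Cre than in Nkx2-5Cre. Actn2, a Z-disc gene, was at 56.6 ± 14.5 CPM in Nkx2-5Cre and 7.9 ± 0.3 in Isl1Cre (-2.62 ± 0.21, adjusted p = 2.83e-07), and Myh7, a myosin heavy chain gene, at 126.3 ± 21.2 and 28.6 ± 5.5 (-2.06 ± 0.17, adjusted p = 4.5e-07). Dcp1b (-2.97 ± 0.26), Acta1 (-2.34 ± 0.21), Asb2 (-2.27 ± 0.17), Casq1 (-2.26 ± 0.33) and Tmem88 (-2.19 ± 0.45) were, with Actn2, the 6 largest negative changes among called genes with an average log2 level of at least 5. The heart tube regulator gene Hand1 was lower as well (-1.90 ± 0.41, adjusted p = 0.00651). At a lower average level, Nodal, a TGF-beta family gene of left-right patterning, was lower by more: it was at 43.1 ± 4.39 CPM in Nkx2-5Cre and listed at 0 in both Isl1Cre libraries, and its target Lefty2 was at 61.26 ± 10.96 against 0.33 ± 0.47. Higher in Isl1Cre were Erdr1 (2.94 ± 0.26), the snoRNA host gene Gas5 (68.3 ± 10.2 against 379.7 ± 6.4 CPM; 2.51 ± 0.14), Supt16 (1.70 ± 0.41), Rgs5 (1.65 ± 0.31) and the imprinted gene Peg3 (1.64 ± 0.29). Counts of Gas5 can include those of the small RNAs in its introns. By Xist and Y gene RNA the Isl1Cre libraries were female and the Nkx2-5Cre libraries male at this stage. Etv2, a regulator of endothelial fate, was at 6.25 ± 4.85 CPM against 106.15 ± 42.44 (4.05 ± 0.48, adjusted p = 2.5e-05). Endothelial-like cells were 4.3% ± 3.0 of Nkx2-5Cre and 12.5% ± 6.0 of Isl1Cre cells.

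In all, 760 genes differed at E7.75, 355 higher and 405 lower in Isl1Cre (365 and 340 with a pseudocount of 10). Of 30 sarcomere genes 25 were lower (28 adjusted over the list alone; median -1.32, camera adjusted p = 7.89e-42), which was the only list called at this stage with an estimated correlation (adjusted p = 0.0141). Ventricular genes were lower in 10 of 17 cases (10 adjusted over the list alone; median -1.38, adjusted p = 1.79e-13, adjusted p = 0.0502 with an estimated correlation). Atrial and inflow genes were lower in 6 of 13 cases (6 lower and 2 higher adjusted over the list alone; median -0.83, adjusted p = 0.00104, adjusted p = 0.0668 with an estimated correlation). Of 25 glycolysis and hypoxia genes 7 were lower (12 adjusted over the list alone; median -0.45, adjusted p = 2.05e-05, adjusted p = 0.11 with an estimated correlation), among them Bnip3 (-1.03 ± 0.15) and Hk2 (-0.96 ± 0.20). The other 9 called lists were calcium handling, oxidative phosphorylation, migration, BMP and TGF-beta and extracellular matrix with negative medians, and S phase, G2 and M phase, endothelial and posterior second heart field with positive ones. Their adjusted p was 0.000215 to 0.0317, and 0.0652 to 0.644 with an estimated correlation. Each library of this stage moved the count by over 1.5 times when left out: to 346 without Nkx2-5Cre replicate 1, 493 without its replicate 2, 318 without Isl1Cre replicate 1 and 377 without its replicate 2. Thinned cells gave 287 and no filter on low values 463.

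At E8.25, 18 of 30 sarcomere genes were lower in Isl1Cre, and 10 of 15 endoderm and 9 of 14 Hox genes were higher. These 3 lists passed with an estimated correlation (adjusted p = 0.0262, 0.0412 and 0.0248). Nppa was at 438.8 ± 151.2 CPM in Nkx2-5Cre and 95 ± 39 in Isl1Cre (-2.24 ± 0.30, adjusted p = 0.000238), and Tnni3 at 449.9 ± 78.1 and 123.8 ± 17.7 (-1.88 ± 0.17, adjusted p = 3.11e-06). The endothelial genes Ramp2 (-2.01 ± 0.40) and Plvap (-1.99 ± 0.48), Chchd10 (-1.79 ± 0.16) and the sterol synthesis gene Msmo1 (-1.72 ± 0.23) were lower too. Endothelial-like cells were 9.6% ± 3.1 of Nkx2-5Cre and 4.3% ± 3.0 of Isl1Cre cells. Krt18, a keratin gene of simple epithelia, was higher (213.9 ± 7.7 against 855.9 ± 8.0 CPM; 1.97 ± 0.16, adjusted p = 2.07e-06), as were Spink1 (2.71 ± 0.34), Ifitm1 (2.18 ± 0.36), Dusp9 (2.14 ± 0.33), Rab33b (2.12 ± 0.24) and Phlda2 (2.04 ± 0.26). From the panel, the second heart field gene Tbx1 (2.16 ± 0.53, adjusted p = 0.0208), Sfrp5 (1.8 ± 0.48), the retinoic acid synthesis gene Aldh1a2 (2.23 ± 0.62, adjusted p = 0.0425) and Cxcr2 (1.51 ± 0.23, adjusted p = 0.000911) were higher. The pacemaker channel gene Hcn4 was lower (-2.62 ± 0.72, adjusted p = 0.0416). Tbx1, Aldh1a2 and Hcn4 lay near the floor, with average log2 levels of 1.51, 1.92 and 1.55 over all libraries. Cardiomyocyte-like cells were 67.7% ± 0.0 of Isl1Cre and 85.0% ± 3.1 of Nkx2-5Cre cells, and unnamed cells 20.4% against 5.3%. Endoderm-like cells made up 7.5% ± 3.0 of Isl1Cre cells and none of the Nkx2-5Cre cells at this stage, and cluster 10, led by Hox genes, 35 of the 186 Isl1Cre cells. Spink1, Ifitm1 and Phlda2, higher here, fell with stage in both lineages, and Nppa, lower here, rose in both. The sarcomere list, lower here, also rose with stage, and the endoderm list, higher here, fell. Whether the Isl1Cre embryo was younger at E8.25 was not tested, so embryo age stays open at this stage.

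At E8.25, 545 genes differed, 267 higher and 278 lower in Isl1Cre; without scaling the split was 304 and 253, and with no filter on low values 179 and 124 (303 genes). Of 14 Hox genes 9 were higher (12 adjusted over the list alone; camera adjusted p = 2.03e-11, and 0.0248 with an estimated correlation). Hoxb6 was at 24.87 ± 2.72 CPM in Isl1Cre and 1.22 ± 1.05 in Nkx2-5Cre, and Hoxc9 at 16.05 ± 1.78 against 0.89 ± 1.26. Of 15 endoderm genes 10 were higher (10 adjusted over the list alone; median 2.71, adjusted p = 2.78e-12, and 0.0412 with an estimated correlation); Cldn6 was at 47.46 ± 4.16 CPM against 0.34 ± 0.17. Retinoic acid genes were higher in 3 of 13 cases (6 adjusted over the list alone; median 0.82, adjusted p = 0.000307, and 0.0412 with an estimated correlation). Surface ectoderm genes were higher in 5 of 6 cases, with Perp lower (median 2.46, adjusted p = 8.42e-07, and 0.0412 with an estimated correlation). This list shares Epcam, Cdh1, Krt8 and Krt18 with the endoderm list, so it is not a separate result. These shared genes were highest in the endoderm-like cluster 9, with Epcam at 274.5 and Krt18 at 3560.0 CPM. Of 30 sarcomere genes 18 were lower (25 adjusted over the list alone; median -0.78, adjusted p = 7.35e-27, and 0.0262 with an estimated correlation). Of 17 ventricular genes 9 (10 adjusted over the list alone; median -0.84, adjusted p = 2.78e-12, and 0.0412 with an estimated correlation). Of 77 oxidative phosphorylation genes 30 were lower and 1 higher (51 and 1 adjusted over the list alone; median -0.42, adjusted p = 1.6e-26, adjusted p = 0.0679 with an estimated correlation), including Cox8a (-0.70 ± 0.10) and Cycs (-0.57 ± 0.10). The posterior second heart field genes Foxf1 (3.43 ± 0.75) and Osr1 (3.19 ± 0.78) were among 6 of 18 that were higher (6 adjusted over the list alone; median 0.58, adjusted p = 0.000359, adjusted p = 0.0884 with an estimated correlation). The other 10 called lists were epithelial junctions, S phase, Wnt, ribosomal proteins and hedgehog with positive medians, and endothelial, calcium handling, outflow tract, extracellular matrix and glycolysis with negative ones; none passed with an estimated correlation (adjusted p = 0.052 to 0.673). The gene count was 251 without Nkx2-5Cre E8.25 replicate 1, 148 without Isl1Cre replicate 1 and 150 without its replicate 2, 118 with thinned cells and 919 by DESeq2.

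At E8.75 the lineages differed in few genes, among them globin genes. Hbb-bh1, an embryonic globin gene, was at 587.41 ± 57.41 CPM, Hba-x at 551.57 ± 57.5 and Hbb-y at 140.47 ± 47.75 in Nkx2-5Cre; all 3 were listed at 0 in both Isl1Cre libraries. The 2 Hbb genes are similar in sequence and can share counts, whereas Hba-x belongs to the other globin family. Of 8 blood genes 4 were lower in Isl1Cre (5 adjusted over the list alone; camera adjusted p = 3.9e-13, and 0.00342 with an estimated correlation), the fourth being the erythroid regulator gene Klf1. Higher in Isl1Cre were Pyy (2.17 ± 0.38), Ramp2 (25.89 ± 17.02 against 96.18 ± 20.52 CPM; 2.00 ± 0.40), Mpv17l (1.42 ± 0.25), Wnk1 (1.32 ± 0.23), Igfbp2 (1.28 ± 0.25) and March5 (1.14 ± 0.18), with adjusted p of 0.00456 to 0.0339. Endothelial-like cells were 6.0% ± 3.6 of Nkx2-5Cre and 10.1% ± 2.0 of Isl1Cre cells. Lower were Spink1 (-1.67 ± 0.34), Tgfb2 (-1.35 ± 0.22), Prps1 (-1.13 ± 0.20) and Mrps12 (-0.76 ± 0.15). Of 19 endothelial genes Ramp2 alone was higher (8 adjusted over the list alone; median 1.18, adjusted p = 4.21e-07, adjusted p = 0.605 with an estimated correlation). Of 10 epiblast genes none (5 adjusted over the list alone; median 0.72, adjusted p = 0.000435, adjusted p = 0.0606 with an estimated correlation), and no oxidative phosphorylation gene passed (median -0.08, adjusted p = 0.00789, adjusted p = 0.774 with an estimated correlation). In all, 34 genes differed, 24 higher and 10 lower. The split was 10 and 19 with no filter on low values, 0 and 3 with thinned cells, and 13 and 15 without Isl1Cre E8.75 replicate 2. The count was 15 without Nkx2-5Cre E8.75 replicate 1, 55 with a pseudocount of 10 and 122 by DESeq2.

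At E9.25, 2 of 16 outflow tract and 5 of 32 extracellular matrix genes were lower in Isl1Cre. Both lists passed with an estimated correlation (adjusted p = 0.032 and 0.0458). Fn1, the fibronectin gene, was at 349.2 ± 100 CPM in Nkx2-5Cre and 79.7 in Isl1Cre (-2.01 ± 0.30, adjusted p = 0.00162), and Isl1 at 28.1 ± 0.3 and 5.0 (-2.21 ± 0.49, adjusted p = 0.0346). Plvap (-2.89 ± 0.59), Pyy (-2.66 ± 0.47), Gngt2 (-2.41 ± 0.51), Hapln1 (-2.17 ± 0.46) and Erdr1 (-1.92 ± 0.32) were lower as well. By Xist and Y gene RNA the Isl1Cre library was male and the Nkx2-5Cre libraries female at this stage. Erdr1 was higher in Isl1Cre at E7.75, where the sexes were reversed, so for it lineage and sex cannot be separated. Higher were Rnd3 (1.75 ± 0.25), Alpk3 (1.66 ± 0.35), the endothelin receptor gene Ednra (1.61 ± 0.38), Dazap2 (1.60 ± 0.34), Lin28a (1.58 ± 0.31), Trmt11 (1.54 ± 0.31) and the heart field regulator gene Tbx5 (16.7 ± 0.1 against 47.8 CPM; 1.54 ± 0.31, adjusted p = 0.0192). Of 16 outflow tract genes Fn1 and Isl1 were lower (4 adjusted over the list alone; median -0.69, camera adjusted p = 1.15e-06, and 0.032 with an estimated correlation). Of 32 extracellular matrix genes 5 (7 lower and 1 higher adjusted over the list alone; median -0.42, adjusted p = 3.85e-06, and 0.0458 with an estimated correlation), with Col18a1 at -1.71 ± 0.21. Of 19 endothelial genes 3 were lower (13 adjusted over the list alone; median -1.93, adjusted p = 1.1e-12, adjusted p = 0.167 with an estimated correlation), beside a share of endothelial-like cells of 2.2% against 17.4% ± 2.8. Of 30 sarcomere genes 2 were higher, Tnni1 (1.06 ± 0.16) and Tnnc1 (0.70 ± 0.15), and none lower (12 adjusted over the list alone; median 0.39, adjusted p = 6.93e-11, adjusted p = 0.145 with an estimated correlation). The other 13 called lists, none of which passed with an estimated correlation (adjusted p = 0.145 to 0.575), included BMP and TGF-beta with Id3 (-1.44 ± 0.19) and blood with Hbb-bh1 at 0.20 ± 0.07 against 169.43 CPM. In all, 104 genes differed, 45 higher and 59 lower. The split depended on the setting: it was 36 and 77 without scaling, but 61 and 53 with a pseudocount of 10, 49 and 32 by edgeR, 92 and 76 with a replicate block (168 genes), and 164 and 67 with no filter on low values. There was no spread within the Isl1Cre group, and the count was 58 without Nkx2-5Cre E9.25 replicate 1, 25 without its replicate 2, 33 with thinned cells, 231 with no filter on low values and 216 by DESeq2.

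**Figure D3:**
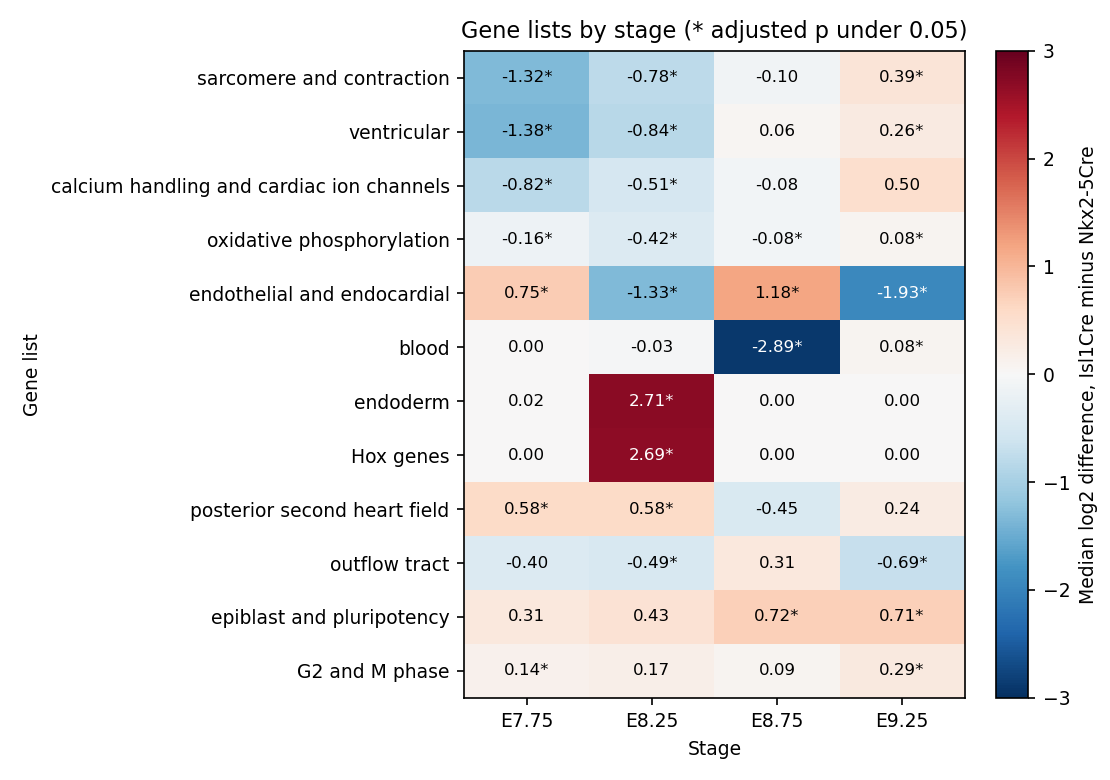
Median log2 difference, Isl1Cre minus Nkx2-5Cre (colour scale), of the tested genes of 12 gene lists (vertical axis) at the 4 embryonic days (horizontal axis); an asterisk marks a camera adjusted p under 0.05. The sarcomere median goes from -1.32 at E7.75 over -0.78 at E8.25 and -0.10 at E8.75 to 0.39 at E9.25.

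With stage, 28 of 30 sarcomere and 13 of 19 calcium handling genes rose in Nkx2-5Cre, and all 30 and 16 of 19 in Isl1Cre. Both lists passed in both lineages with an estimated correlation. In Nkx2-5Cre 2639 genes changed with embryonic day, 1404 up and 1235 down, and in Isl1Cre 2479, 1388 up and 1091 down. Among called genes with an average log2 level of at least 5, Nppa had the largest rise in both, by 3.87 ± 0.19 log2 per day in Nkx2-5Cre (from 13.1 ± 6.0 to 1207.2 ± 143.3 CPM) and 5.42 ± 0.23 in Isl1Cre (from 3.2 ± 0.6 to 1280.5 CPM). Next in Nkx2-5Cre were Trdn (3.12 ± 0.35), Cox6a2 (3.12 ± 0.16), Myl2 (2.76 ± 0.12), Cck (2.63 ± 0.12) and Chchd10 (2.59 ± 0.10). In Isl1Cre they were Trdn (4.57 ± 0.43), Myl2 (4.37 ± 0.14), Cck (4.29 ± 0.15), Cox6a2 (4.0 ± 0.19) and Myh7 (3.88 ± 0.13). The interferon-induced gene Ifitm1 had the largest fall of that set in both (-4.40 ± 0.23 and -4.80 ± 0.27). It was followed in Nkx2-5Cre by Spink1 (-2.79 ± 0.21), the Wnt inhibitor gene Sfrp5 (-2.71 ± 0.30), Phlda2 (-2.30 ± 0.16), Tmem88 (-2.12 ± 0.28) and the Nodal co-receptor gene Cfc1 (-2.06 ± 0.22). In Isl1Cre it was followed by Spink1 (-2.98 ± 0.26), Phlda2 (-2.69 ± 0.20), Emb (-2.65 ± 0.17) and Sfrp5 (-2.65 ± 0.36). The heart field genes Fgf8 (-1.93 ± 0.18 and -1.39 ± 0.22) and Tbx1 (-1.79 ± 0.33 and -2.22 ± 0.40) fell in both, as did Cxcr2 (-0.89 ± 0.15 and -0.83 ± 0.18). Isl1 fell in Isl1Cre (-1.67 ± 0.31, adjusted p = 0.000509) and was at -0.62 ± 0.25 (adjusted p = 0.0826) in Nkx2-5Cre. The adjusted p of these largest changes lay between 1.2e-13 (Myl2 in Isl1Cre) and 2.79e-05 (Tmem88 in Nkx2-5Cre).

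Of 30 sarcomere genes 28 rose in Nkx2-5Cre (28 adjusted over the list alone; median 0.90 log2 per day, camera adjusted p = 4.67e-29, and 0.0418 with an estimated correlation). In Isl1Cre all 30 rose (median 2.07, adjusted p = 5.1e-50, and 0.00807 with an estimated correlation). Of 19 calcium handling genes 13 and 16 rose and 1 fell in each (medians 1.12 and 2.09, adjusted p = 1.17e-06 and 6.22e-11, and 0.0475 and 0.00975 with an estimated correlation), among them Slc8a1 (1.30 ± 0.15 and 2.66 ± 0.18), the sodium-calcium exchanger gene. Of 77 oxidative phosphorylation genes 55 rose and 1 fell in Nkx2-5Cre (median 0.34, adjusted p = 3.2e-23, adjusted p = 0.0751 with an estimated correlation). In Isl1Cre 69 rose (median 0.53, adjusted p = 1.91e-33, and 0.0398 with an estimated correlation). Of 72 ribosomal protein genes 52 and 51 fell and none rose (medians -0.29 in both, adjusted p = 2.19e-23 and 2.57e-19, adjusted p = 0.0984 and 0.128 with an estimated correlation). Of 18 posterior second heart field genes 9 and 11 fell (medians -0.71 and -1.64, adjusted p = 1.11e-06 and 1.62e-06, and 0.0475 and 0.0398 with an estimated correlation), including Aldh1a2 (-2.49 ± 0.39 and -3.61 ± 0.47). Of 15 endoderm genes 13 fell and 1 rose in each lineage (medians -1.98 and -2.13, adjusted p = 1.43e-08 and 9.11e-11; adjusted p = 0.075 and, passing, 0.0398 with an estimated correlation), beside endoderm-like cells that were seen in the E7.75 libraries and at E8.25 in Isl1Cre. Of 14 Hox genes 4 fell in Nkx2-5Cre (4 adjusted over the list alone; adjusted p = 0.00766, adjusted p = 0.0984 with an estimated correlation). In Isl1Cre 6 fell (6 adjusted over the list alone; adjusted p = 0.000188, and 0.0452 with an estimated correlation). Hedgehog genes fell in 6 of 10 cases in each lineage (medians -1.03 and -1.37, adjusted p = 0.000927 and 0.00152, and 0.0475 and 0.0398 with an estimated correlation). Retinoic acid genes fell in 7 and 8 of 13 cases (medians -1.05 and -1.79, adjusted p = 0.000436 and 1.48e-05, and 0.0475 and 0.0225 with an estimated correlation). S phase genes fell in 8 of 36 cases in Nkx2-5Cre, with 1 rise (median -0.18, adjusted p = 0.00836, adjusted p = 0.0885 with an estimated correlation). In Isl1Cre 16 of them fell (median -0.41, adjusted p = 1.21e-08, and 0.00975 with an estimated correlation), including Pcna (-0.75 ± 0.10). Adjusted over the list alone, the counts in Nkx2-5Cre and Isl1Cre were 14 and 17 calcium handling, 67 and 72 oxidative phosphorylation genes that rose, and 63 and 58 ribosomal, 10 and 11 posterior second heart field, 13 and 13 endoderm, 7 and 6 hedgehog, 8 and 8 retinoic acid and 8 and 19 S phase genes that fell. In each lineage 21 lists were called, and 6 in Nkx2-5Cre and 10 in Isl1Cre with an estimated correlation.

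By Xist and Y gene RNA, the Isl1Cre libraries were female at E7.75 and E8.25 and male at E8.75 and E9.25, so stage and sex cannot be separated there. The Nkx2-5Cre libraries were male, female, male and female, so the difference of the slopes carries sex as well. With the libraries of a group pooled to 1 unit, 6 genes were called in Nkx2-5Cre and 527 in Isl1Cre, and with thinned cells 990 and 1122. The Nkx2-5Cre count was 1707 without its E7.75 replicate 2 and 1591 without its E9.25 replicate 2.

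The rise of contractile genes was steeper in Isl1Cre than in Nkx2-5Cre, by a test of the difference between the slopes. The share of cardiomyocyte-like cells had slopes of 67.66 points per day in Isl1Cre and 50.63 in Nkx2-5Cre (the latter did not pass), and stood at 97.8% and 82.6% at E9.25. The difference of the share slopes was not tested. The test of gene slopes called 275 genes, 201 with a more positive and 74 with a more negative slope in Isl1Cre. Among called genes with an average log2 level of at least 5, the largest positive differences were in Dcp1b (2.12 ± 0.25 log2 per day), Acta1 (1.97 ± 0.21), Actn2 (1.92 ± 0.20), Myh7 (1.88 ± 0.17), Alpk3 (1.85 ± 0.29) and Coq9 (1.73 ± 0.28). The panel genes Myl2 (1.61 ± 0.18), Nppa (1.55 ± 0.30), Myh6 (1.08 ± 0.17), Myl7 (0.69 ± 0.10), Nkx2-5 (0.68 ± 0.16) and Tnnt2 (0.67 ± 0.12) were also called (7 of 23 panel genes, 9 adjusted over the list alone). The most negative of that set were in Erdr1 (-2.79 ± 0.26), Gas5 (-1.61 ± 0.14), Tgs1 (-1.48 ± 0.30), Cramp1l (-1.47 ± 0.27), Tmppe (-1.46 ± 0.31) and the BMP target gene Id3 (-1.25 ± 0.15). Erdr1 was higher in Isl1Cre at E7.75, where Isl1Cre was female and Nkx2-5Cre male, and lower at E9.25, where the sexes were reversed. Its slope difference cannot be separated from sex. Adjusted p ran from 1.13e-06 (Gas5) to 0.0272 (Nkx2-5). The slope was more positive for 25 of 30 sarcomere genes (28 adjusted over the list alone; median 1.21, camera adjusted p = 4.04e-51, and 0.00754 with an estimated correlation). It was also more positive for 8 of 17 ventricular genes (13 adjusted over the list alone; median 1.29, adjusted p = 4.09e-16, and 0.024 with an estimated correlation). The same held for 5 of 19 calcium handling genes, with 1 more negative (9 and 1 adjusted over the list alone; median 0.86, adjusted p = 1.58e-05, and 0.0415 with an estimated correlation), and for 3 of 13 atrial and inflow genes (4 adjusted over the list alone; median 0.69, adjusted p = 6.95e-05, and 0.0315 with an estimated correlation). Of 36 S phase genes 3 had a more negative slope (4 adjusted over the list alone; median -0.34, adjusted p = 2.46e-06, and 0.024 with an estimated correlation). The other 5 called lists, oxidative phosphorylation, endothelial, endoderm, surface ectoderm and glycolysis, did not pass with an estimated correlation (adjusted p = 0.312 to 0.467). Pooled to 1 unit per group, limma called 0 genes (577 at an unadjusted p under 0.05; with all 15 libraries edgeR called 311 and DESeq2 515). The count was 146 without Nkx2-5Cre E9.25 replicate 2, 167 without Isl1Cre E7.75 replicate 1, 852 without the Isl1Cre E9.25 library and 95 with thinned cells; Cramp1l was at 0.06 without the Isl1Cre E9.25 library.

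Within cardiomyocyte-like cells, few contractile genes differed between the lineages, while Isl1, Cxcr2 and Lin28a did. No E7.75 library had enough of these cells, so this contrast covers E8.25 to E9.25 only. In all cells the sarcomere median was lowest at E7.75 (-1.32). The small contractile difference here can therefore not be put down to the choice of cells alone. Isl1 was lower in Isl1Cre (-1.37 ± 0.30, adjusted p = 0.0291), Nkx2-5 higher (0.48 ± 0.11, adjusted p = 0.0388) and Cxcr2 higher (0.97 ± 0.19, adjusted p = 0.0179), whereas Tnnt2 was at -0.14 ± 0.08 (adjusted p = 0.472) and Myh7 at 0.04 ± 0.14 (adjusted p = 0.941); 3 of 20 tested panel genes passed, and 4 adjusted over the list alone. Higher were Mpv17l (1.64 ± 0.18), Wnk1 (1.26 ± 0.12), March5 (1.14 ± 0.13), Slfn5 (1.05 ± 0.15), Sema4b (1.03 ± 0.20) and Lin28a (1.03 ± 0.18). Lower were the galanin gene Gal (-1.36 ± 0.28), the antisense transcript Atcayos (-1.07 ± 0.23), the Wnt agonist gene Rspo3 (-1.06 ± 0.24), Itga6 (-0.99 ± 0.19), Tgfb2 (-0.97 ± 0.16) and Coq7 (-0.91 ± 0.19). Of 10223 genes, 109 differed, 72 higher and 37 lower. Of 77 oxidative phosphorylation genes 2 were higher, Sdhc among them, and none lower, with 12 lower and 2 higher adjusted over the list alone (median -0.17, camera adjusted p = 1.49e-12, adjusted p = 0.603 with an estimated correlation). The sarcomere list of 30 genes had 1 lower gene, Tnni3 (5 adjusted over the list alone; median -0.16, adjusted p = 1.43e-05, adjusted p = 0.603 with an estimated correlation). Of 9 epiblast genes Lin28a and Sall4 were higher (4 adjusted over the list alone; median 0.52, adjusted p = 0.00175, adjusted p = 0.229 with an estimated correlation). The other 7 called lists did not pass with an estimated correlation either (adjusted p = 0.603 to 0.61). At E8.25 cluster 4 held 103 of 126 cardiomyocyte-like cells (81.7%) in Isl1Cre and 9 of 159 (5.7%) in Nkx2-5Cre, where cluster 1 was the largest (39.0%). The count was 49 without cluster 4, 42 without the E8.25 libraries, 5 with groups pooled to 1 unit, 10 with no filter on low values, 34 by edgeR and 211 by DESeq2. With single libraries left out, it was lower by over 1.5 times for 9 of the 11, and it was 114 without Nkx2-5Cre E8.75 replicate 2. It was 61 and 66 without Nkx2-5Cre E8.25 replicates 1 and 2, 28 without Nkx2-5Cre E8.75 replicate 1, and 67 and 68 without Nkx2-5Cre E9.25 replicates 1 and 2. It was 53 and 47 without Isl1Cre E8.25 replicates 1 and 2, and 47 and 61 without Isl1Cre E8.75 replicates 1 and 2.

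With stage, 13 of 77 oxidative phosphorylation and 3 of 16 ventricular genes rose in cardiomyocyte-like cells. These slopes cover E8.25 to E9.25, as no E7.75 library had enough of these cells. No list passed with an estimated correlation (adjusted p = 0.317 for both). Nppa (2.35 ± 0.36 log2 per day, adjusted p = 0.00214), Rspo3 (1.83 ± 0.32), Fxyd1 (1.76 ± 0.31), the ketone body enzyme gene Oxct1 (1.71 ± 0.29), Myl2 (1.61 ± 0.21, adjusted p = 0.000511) and Peg12 (1.46 ± 0.32) rose most among called genes with an average log2 level of at least 5, and Myh7 rose by 1.23 ± 0.19. Spink1 (-2.0 ± 0.42), Dqx1 (-1.92 ± 0.46), the carbonic anhydrase gene Car4 (-1.81 ± 0.24), Lin28a (-1.65 ± 0.27), Phlda2 (-1.63 ± 0.35) and Kifc2 (-1.52 ± 0.21) fell most in that set, and Sfrp5 (-2.20 ± 0.52) and Fgf8 (-1.36 ± 0.27) fell too. Tnnt2 (0.16 ± 0.13, adjusted p = 0.605) did not pass; 6 of 20 panel genes did, and 8 adjusted over the list alone. Of 77 oxidative phosphorylation genes 13 rose and none fell (47 adjusted over the list alone; median 0.33, camera adjusted p = 2.43e-25, adjusted p = 0.317 with an estimated correlation), with Ndufc2 at 0.80 ± 0.13 and Cox6a2 at 1.40 ± 0.28. Of 16 ventricular genes 3 rose (9 adjusted over the list alone; median 0.67, adjusted p = 2.22e-07, adjusted p = 0.317 with an estimated correlation). Among 30 sarcomere genes 4 rose (7 adjusted over the list alone; median 0.24, adjusted p = 2.83e-06, adjusted p = 0.463 with an estimated correlation). The other 10 called lists did not pass with an estimated correlation (adjusted p = 0.317 to 0.728). In all, 189 genes changed, 127 up and 62 down. The makeup of the class changed as well: cluster 6 held 42.9% of it at E8.75 and 1.3% at E9.25 in Nkx2-5Cre, and 23.0% and 1.1% in Isl1Cre. The count was 55 without cluster 4, 3 with groups pooled to 1 unit, 17 with no filter on low values and 472 by DESeq2. Without the Isl1Cre E9.25 library it was 45, without Nkx2-5Cre E9.25 replicate 2 79, and without Isl1Cre E8.25 replicates 1 and 2 63 and 98.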

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

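Of the tests in this part, those of read depth at E7.75, of the Nkx2-5Cre change from E7.75 to E8.25 and of the loss of an Isl1 or Nkx2-5 copy were chosen after the result they concern was seen. Each gene and gene list counted in the next paragraph is listed because its trend with embryonic day differed between Isl1Cre and Nkx2-5Cre by a test of the difference of the slopes.

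The trends differed in 275 genes and 10 gene lists, of which 5 lists were also called with an estimated correlation. The slope was more positive in Isl1Cre for Dcp1b (2.12 log2 per day), for the sarcomere genes Acta1 (1.97), Actn2 (1.92) and Myh7 (1.88), and for Alpk3 (1.85) and Coq9 (1.73). It was also more positive for Myl2 (1.61), Nppa (1.55), Myh6 (1.08), Myl7 (0.69), Nkx2-5 (0.68) and Tnnt2 (0.67). It was more negative for Erdr1 (-2.79), Gas5 (-1.61), Tgs1 (-1.48), Cramp1l (-1.47), Tmppe (-1.46) and Id3 (-1.25). For Erdr1, lineage and sex cannot be separated, as it differed in opposite directions at E7.75 and E9.25, where the sexes were opposite. Cramp1l was at 0.06 without the Isl1Cre E9.25 library, and without it the count of genes was 852. It was 146 without Nkx2-5Cre E9.25 replicate 2 and 167 without Isl1Cre E7.75 replicate 1. Actn2 lay at 56.6 ± 14.5 CPM in Nkx2-5Cre and 7.9 ± 0.3 in Isl1Cre at E7.75 (SD, n = 2), and at 270.5 and 299.3 CPM at E9.25. Gas5 lay at 68.3 ± 10.2 and 379.7 ± 6.4 CPM at E7.75, and at 348.7 and 335.2 CPM at E9.25. For these 2 genes the levels were apart at the first stage and close at the last. The share of cardiomyocyte-like cells had slopes of 67.66 points per day in Isl1Cre and 50.63 in Nkx2-5Cre, whose difference was not tested, and stood at 97.8% and 82.6% at E9.25.

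The first pattern is the separation of the lineages at E7.75, where 760 genes differed and most cells of each lineage formed their own cluster. Read depth is argued against: after cells were thinned, 0.56% (1 of 177) of the Nkx2-5Cre cells fell in the cluster of most Isl1Cre cells. Sex (male in Nkx2-5Cre, female in Isl1Cre) is argued against as the whole cause, since 73.8% of the 760 genes changed the same way at E8.25, where the libraries of both lineages were female (56.4% of all tested genes did). The share was lower at E8.75 (63.7%), where both were male, and at E9.25 (55.4%), where the sexes were reversed. For these later stages the share of all tested genes was not computed, so a part played by sex stays open. A younger Isl1Cre embryo stays open: 36.1% of the 760 genes changed against the Nkx2-5Cre slope after E8.25 and 50.8% against that of Isl1Cre, but genes such as Actn2 rose to E8.25 and E8.75 and then fell (the slope had the sign of the earlier change for 57.8%), and against the change from E7.75 to E8.25 it was 48.4% (58.8% and 60.1% of the 204 and 198 genes with a 2-fold change or more, by the Nkx2-5Cre E7.75 library used). A difference between 2 embryos, the way cells were picked and the lineage itself stay open, since each group probably comes from 1 embryo.

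The second pattern is the lineage contrast over the 4 stages. For each of 6 counts, 100 splits of the libraries were taken, and only 1, the real one, gave as many genes. The counts were 784 (highest other 140) for lineage and 275 (121) for the difference of slopes. They were 2639 (2079) and 2479 (1698) for the stage trends in Nkx2-5Cre and Isl1Cre. In cardiomyocyte-like cells they were 109 (18) for lineage and 189 (9) for stage. A split that parts the libraries of 1 embryo widens the spread within groups, which favours the real assignment in advance. So these splits cannot exclude chance and do not address differences between embryos. When whole groups were swapped within stages, 1 of the 8 assignments, the real one, gave as many as 784 genes (highest other 453, with E9.25 swapped), and 8 are too few for a share under 0.05. DNA carried over around the Cre insertions cannot be told apart from lineage for part of the genes: 42 of 759 called genes lay within 20 Mb of Isl1 or Nkx2-5, a share 1.41 times that of tested genes (95% interval 1.02 to 1.88). Lineage and embryo, including the age of the embryo, therefore both remain open as candidate explanations.

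The third pattern is the level of the 2 driver genes, Isl1 and Nkx2-5, which the Cre insertions may alter. Isl1 was lower in Isl1Cre within cluster 2 as well, by -2.49 log2 on average over 10 libraries (-3.31 at E8.25, from 1 Isl1Cre library with 6 cells of the cluster, and -2.23 and -1.92 at E8.75 and E9.25; exact permutation p = 0.0185, the smallest that 54 arrangements can give), so the shares of the clusters are argued against as the cause, while makeup within cluster 2 was not tested. Loss of 1 Isl1 copy would give about -1. In cluster 2, the cardiomyocyte-like cluster with most Isl1, the difference lay below -1 at each of these stages (exact permutation p = 0.0185 against -1). Both exact tests permuted libraries, probably of 1 embryo per group, and Isl1 was at 4.3 to 19.7 CPM in the Isl1Cre libraries tested. They cannot exclude loss of 1 copy beside a difference between embryos, so it stays open. Over all cells it stays open too, as the difference was -1.0 ± 0.21, 0.01 SE from -1 (-0.57, -0.43, -0.77 and -2.21 at the 4 stages), and -1.37 ± 0.30 in cardiomyocyte-like cells. Loss of 1 Nkx2-5 copy in Nkx2-5Cre would put Nkx2-5 at 1 log2 higher in Isl1Cre, and the measured 0.28 ± 0.09 lay -8.38 SE from that; at E7.75 and E8.25 it was at -0.28 and 0.09, but at E8.75 and E9.25 at 0.67 ± 0.16 and 0.66 ± 0.20, -2.04 and -1.74 SE from 1, too near to exclude such a loss with 7 degrees of freedom, so it stays open there. How either Cre was inserted is not given, and a biological difference stays untested.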

How the results depend on the processing

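Counts over the 15 libraries are given first for the analysis reported and then for each alternative. The pseudocounts, the unscaled values, leaving out E7.75, E8.25 or cluster 4, and pooling in the list tests were chosen after seeing the data. So was the use of edgeR, the planned main test, as an alternative to limma. Over all alternatives, 209 of 270 gene counts were within 1.5 times and 61 were not. Of 162 values of the class shares 153 were the same, 4 passed the threshold newly and 5 no longer. Of 1166 for gene lists 955 were the same, 182 no longer passed, 13 passed newly, 14 counts moved and 2 reversed, and of 5381 for named genes 5011 were the same, 327 no longer passed, 41 passed newly and 2 reversed. Except where an alternative leaves out libraries, cells or counts by construction, the cause was not tested.

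With a pseudocount of 10, 55 genes differed at E8.75 (34 reported). With no filter on low values there were 463 at E7.75 (760), 303 at E8.25 (545), 231 at E9.25 (104), and 10 and 17 for lineage and stage in cardiomyocyte-like cells (109 and 189). By edgeR 34 differed by lineage in cardiomyocyte-like cells. By DESeq2 there were 515 for the difference of slopes (275), 919 at E8.25, 122 at E8.75, 216 at E9.25, and 211 and 472 for lineage and stage in cardiomyocyte-like cells. With groups pooled to 1 unit, limma called 0 for lineage (784; 874 at an unadjusted p under 0.05), 6 and 527 for stage in Nkx2-5Cre and Isl1Cre (2639 and 2479), 0 for the difference of slopes (577 unadjusted), and 5 and 3 in cardiomyocyte-like cells. Thinning cells to 5000 counts also left out shallower cells, so that 1282 of 1332 remained. It gave 216 for lineage, 990 and 1122 for stage in Nkx2-5Cre and Isl1Cre, 95 for the difference, and 287, 118, 3 and 33 at E7.75, E8.25, E8.75 and E9.25. Without cluster 4 there were 49 by lineage and 55 by stage in cardiomyocyte-like cells. Without the E7.75 libraries lineage gave 260, and without those of E8.25 458, and 42 in cardiomyocyte-like cells. At E9.25 the split of 45 higher and 59 lower was 36 and 77 without scaling and 164 and 67 with no filter, and at E8.75 24 and 10 became 10 and 19 with no filter. No list called in any contrast changed the sign of its median with RLE scaling or without scaling. With a replicate block, 168 genes differed at E9.25; no other count moved by over 1.5 times. The replicate numbers do not pair the libraries (correlations over 21 pairs of groups from -0.03 to 0.17, median 0.02).

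The lists called with an estimated correlation were 0 for lineage (16), 6 and 10 for stage in Nkx2-5Cre and Isl1Cre (21 each), 5 for the difference (10), 1, 6, 1 and 2 at E7.75 to E9.25 (13, 18, 4 and 17), and 0 and 0 by lineage and stage in cardiomyocyte-like cells (10 and 13). By fry they were 2 at E8.75, 3 at E9.25, and 0 and 1 in cardiomyocyte-like cells. In 4 cases the direction reversed: Hox genes by lineage with pooled groups (adjusted p = 0.843), blood in the difference of slopes by fry (adjusted p = 0.0154), Myh7 by lineage without E7.75 (0.07), and Cramp1l in the difference without Isl1Cre E9.25 replicate 1 (0.06, with -1.67 the lowest value when other libraries were left out).

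With each library left out in turn, lineage gave 529 to 910 genes and stage in Isl1Cre 1823 to 2849. Stage in Nkx2-5Cre gave 1591 (without Nkx2-5Cre E9.25 replicate 2) to 2778, and 1707 without Nkx2-5Cre E7.75 replicate 2. The difference gave 146 (without Nkx2-5Cre E9.25 replicate 2) to 852 (without Isl1Cre E9.25), and 167 without Isl1Cre E7.75 replicate 1. E7.75 gave 318 to 856, with 346 and 493 without Nkx2-5Cre replicates 1 and 2 and 318 and 377 without Isl1Cre replicates 1 and 2. E8.25 gave 148 to 555, with 251 without Nkx2-5Cre replicate 1 and 148 and 150 without Isl1Cre replicates 1 and 2. E8.75 gave 15 (without Nkx2-5Cre replicate 1) to 39, and E9.25 25 to 139, with 58 and 25 without Nkx2-5Cre replicates 1 and 2. In cardiomyocyte-like cells lineage gave 28 to 114 and stage 45 to 261, the libraries being named beside those counts in the report. Stage in cardiomyocyte-like cells gave 261 without Nkx2-5Cre E8.25 replicate 2. Share differences by lineage were -7.13 to -1.0 points for cardiomyocyte-like, -3.12 to 2.31 for endothelial-like and 1.68 to 2.99 for endoderm-like cells. Slopes in Nkx2-5Cre and Isl1Cre were 37.91 to 61.19 and 59.76 to 87.01 points per day for cardiomyocyte-like, 4.94 to 8.22 and -5.8 to -1.2 for endothelial-like, and -4.52 to -1.96 and -7.97 to -6.18 for endoderm-like cells.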

Other observations

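This part holds values without tests, and the genes named here were chosen after their values were seen.

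A group of Isl1Cre cells at E8.25 carried RNA of posterior Hox genes and of Pitx1 and Tbx4. Cluster 10 held 37 cells, 35 of them from the 186 Isl1Cre cells of E8.25 (18.8%). Hoxaas3, Pitx1, the endothelial marker Etv2 (165.7 CPM), Hoxb6, Cdx4 and Hoxc9 were among the leading genes of this cluster. Its mean level was 42.7 CPM for Tbx4, a regulator gene of the hindlimb and allantois, which was at most 1.5 CPM in each other cluster. Foxf1, a gene of splanchnic mesoderm, was at 62.3 CPM (22.2 in cluster 4, the next highest) and Osr1 at 42.9 CPM (26.9 in cluster 5, the next highest). Cardiac actin (Actc1) was at 767.5 CPM, against 4989.3 to 8661.2 in the cardiomyocyte-like clusters. The cluster met the rule for no cell class.

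Globin RNA was present in cells named cardiomyocyte-like. After E7.75, Hba-x had a mean of 206.2 CPM in Nkx2-5Cre cardiomyocyte-like cells, with a count in 29.5% of 481 cells, and 24.3 CPM in endothelial-like cells, with a count in 18.0% of 61. These are means over stages that differ: over all cells Hba-x was at 551.57 CPM in Nkx2-5Cre at E8.75 and 0.31 at E9.25, and in Isl1Cre at 0 and 42.73. Tnnt2 was at 581.3 CPM in Nkx2-5Cre and 785.0 CPM in Isl1Cre endothelial-like cells, against 5972.7 and 5444.7 CPM in cardiomyocyte-like cells.

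Each group carried mainly the RNA of 1 sex. Xist was present in the libraries of 4 of the 8 groups, Nkx2-5Cre at E8.25 and E9.25 and Isl1Cre at E7.75 and E8.25, and the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty in those of the other 4. In the libraries with Xist, 16 cells had a Y count, 14 of them in Nkx2-5Cre E8.25. Of the 16 cells 31.2% lacked Xist, against 17.5% of the other 716, and their median Y level was 8.4 CPM, against 93.9 CPM in cells with a Y count in the other libraries.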
